A study of Sparus aurata with 8 samples.

How the data were processed

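Gut RNA pools from gilthead sea bream (Sparus aurata), a marine farmed fish, were hybridised to 1-colour oligonucleotide arrays. Per the labels' protocols, juveniles of 10.6 g were fed a control diet or a diet with spray-dried porcine plasma (SDPP), a protein feed ingredient made from pig blood, for 95 days in 4 tanks per diet of 50 fish each, and 10 fish per tank were sampled. Titles, source names and the series text name the gut (anterior intestine), whereas the tissue field and the RNA extraction protocol name skin. The arrays were treated as gut here, and the conflict was not resolved from the data because no probe could be given a gene name. Per the labels' protocols, 200 ng of total RNA from samples with an integrity number above 8.0 was labelled with Cy3 together with spike-in RNA. The labels give 4 pools per diet but not how many fish formed a pool or whether a pool stands for a tank, so p-values measure only the spread between these pools.

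The spot intensities were deposited as scanner output of Agilent Feature Extraction 10.7.3.1, per the file headers. The processed signal is a background-subtracted intensity on a linear scale, and the files also give the median signal, the median local background, and flags for outlier spots and for spots well above background. Each array held 45220 spots, of which 43803 were not controls. These stood for 28793 distinct probes and 15156 sequence names, 6605 of them with 3 probes and 8376 with 1. No spot was saturated on any array. The deposited value table of the whole series, on a log2 scale, equals the log2 of the background-subtracted signal to within 5e-09, with no scaling between arrays, and 22.6% of its cells hold no value. Its columns have medians of 10.3, 10.0, 9.59 and 10.3 for control pools 1 to 4 and of 9.81, 10.3, 10.2 and 9.53 for SDPP pools 1 to 4. Its scale and centring are thereby known, and a 1-colour design leaves no direction to settle.

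Log2 processed signals were set relative to each array's 75th percentile over non-control spots, outlier spots were left out, and spots of 1 probe were averaged. A probe counted as well above background on an array if at least 50% of its spots did, and 12396 probes that met this on all 4 arrays of at least 1 diet were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. A probe past that threshold is termed called. For counts of transcripts, the brightest tested probe of each sequence name stood for it and p-values were adjusted over 6798 transcripts. Where a probe was not well above background on any array of 1 diet, a fold was given as a bound, with each dim array set to the higher of the probe's own signal and the lowest signal among spots well above background on that array. Array-level values were compared with exact permutation tests, and the separation of the diets was tested over the 35 splits of 8 arrays into 4 and 4. The number of arrays limits the precision.

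On simulated arrays with the means and spreads of the 12396 probes, 4 against 4, limma recovered 5 of 50 probes changed 1.5-fold, 30 of 50 changed 2-fold, 49 of 50 changed 4-fold and 45 of 50 changed 8-fold, with 3 false calls among 132. With no change simulated it called 1 probe and gave 597 at an unadjusted p below 0.05. The simulated probes varied independently, whereas probes of real pools can vary together, so these counts do not give the rate of false calls here.

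None of the 15156 sequence names matched a symbol, synonym or accession among the 32006 genes of the RefSeq table used here. The 31 gene lists and the tissue and cell type markers fixed before the data were examined could therefore not be applied, and no gene is named. The rule fixed for named genes left out probes without a gene name, so as fixed it gave no transcript. It was extended here to sequence names, limited to 2 in each direction, a choice not fixed beforehand. The transcripts given have the largest fitted log2 differences, whether or not measured above background on both diets. They were taken from called probes whose 4 SDPP arrays all lay on 1 side of the 4 control arrays.

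Alternatives fixed before the data were examined covered background correction, scaling, the filter on dim probes, pool number and slide as blocks, array weights, a trended variance prior, an unmoderated test and leaving out each array. The background alternative was normexp with an offset of 50 on the median signal, since the mean signal is not among the columns used here. Slide as a random block, spike-in scaling over the 5 of 10 spike-in probes above background on all arrays, every choice of 3 arrays against 3, and 3 further choices of arrays were added after seeing the data. All arrays were scanned on 1 day, so scan date was not a batch. The 8 arrays lay on 6 slides. Slide 1 held control pool 1 with SDPP pool 3, and slide 2 held control pool 2 with SDPP pool 4. On both, the control pool was at position 1 and the SDPP pool at position 2. The other 4 arrays were alone on their slides, at position 1. Feature Extraction did not accept the grid on control pool 1 and on SDPP pools 1, 2 and 3.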

Results

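Gene expression was measured in 8 pools of gut RNA, 4 from fish on the control diet and 4 from fish on the SDPP diet. The series title frames the question as metabolic and immune processes in the gut at the transcript level. The number of non-control spots well above background was 18951, 24803, 30641 and 21806 on control pools 1 to 4 and 24369, 15488, 17817 and 22753 on SDPP pools 1 to 4. The mean difference, SDPP minus control, was -3943.5 spots, with 24050 ± 5001 on the control diet and 20107 ± 4153 on the SDPP diet (SD, n = 4; two-sided exact permutation p = 0.257), a difference within the spread between pools. Over 5893 tested probes printed in 2 copies, the SD between copies within an array, as a root mean square over probes, ran from 0.112 to 0.359 on the log2 scale. The SD between pools of 1 diet, after copies were averaged, had a median of 0.254 over all tested probes. A root mean square gives noisy probes more weight than a median does, so these values do not rank the 2 sources of spread.

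The 8 pools separated by diet. The root mean square log2 difference per probe was 0.862 between pools of different diets, 0.506 between control pools and 0.676 between SDPP pools. The between-diet excess of 0.272 was the largest of the 35 splits of the arrays, with 0.136 for the next, which gives a one-sided exact permutation p of 0.0286, the smallest these splits allow. The tested probes were chosen by detection within each diet, which favours the real split, so this p is not strictly exact. Without control pool 1 the exact p was 0.0571. Principal component 1 held 58.9% of the variance and component 2 held 19.4%. On component 1 the control pools lay between -46.6 and -23.1, and SDPP pools 3, 1, 2 and 4 lay at 0.37, 17.0, 45.2 and 86.4. SDPP pool 4 was the farthest from the control mean, at a root mean square log2 difference of 1.14, against 0.617, 0.805 and 0.652 for SDPP pools 1, 2 and 3.

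**Figure D1:**
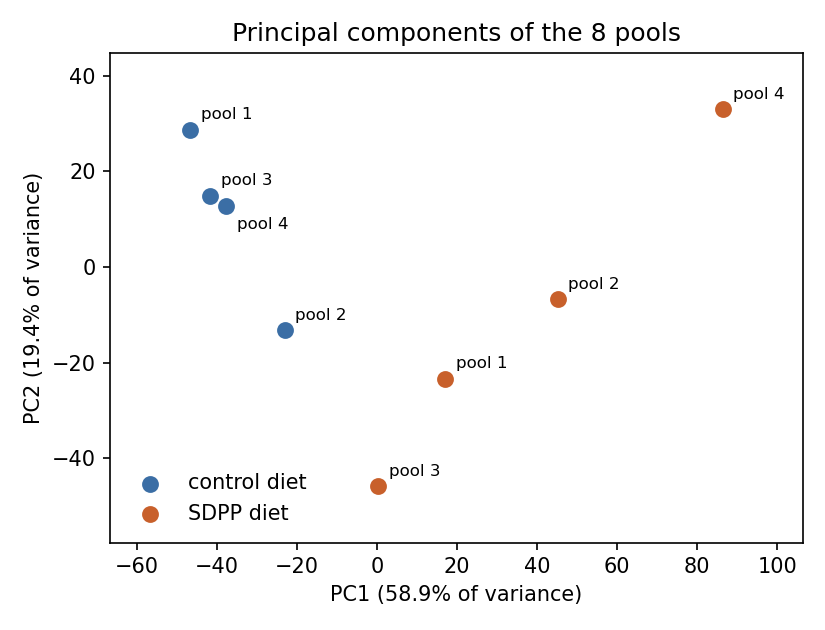
Principal components 1 and 2 of log2 signal over 12325 tested probes with values on all arrays, 1 point per pool, coloured by diet, with the share of variance on each axis. All 4 SDPP pools lie to the right of the control pools on component 1, from 0.37 for pool 3 to 86.4 for pool 4.

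Transcripts went both ways on the SDPP diet. Of 12396 tested probes, limma called 2731 at an adjusted p below 0.05, 1715 higher and 1016 lower on SDPP. At the level of sequence names, 1489 of 6798 transcripts were called, 915 higher and 574 lower. That count was 520 without control pool 4, 584 without SDPP pool 2, 666 without control pool 3, 772 without control pool 1 and 804 without SDPP pool 1, but 1134 without SDPP pool 4, 1472 without control pool 2 and 2169 without SDPP pool 3. Its balance turned to 594 higher and 813 lower with the 75th percentile taken over probes above background on all arrays, and to 217 and 768 with the deposited values on their own scale. Most fitted changes were moderate, with a median of 1.70-fold among the called probes and a 90th percentile of 3.34-fold. The fitted change was at least 2-fold in 377 probes called higher and 520 called lower, of which 82 and 377 were not well above background on every array, so that the size of their change is uncertain. At 8-fold the counts were 15 and 27, of which 8 and 24 were not well above background on every array. The 4 arrays of 1 diet lay entirely on 1 side of the other 4 for 2578 of the called probes, which the call itself largely fixes. Over all tested probes the share was 30.1%, where chance gives 2.86% if the 8 pools are separate samples. The filter on dim probes used the diets and favours such probes, so the 2 shares are not strictly comparable.

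The balance of higher and lower calls depended on signal and on scaling. Among the 3099 brightest probes 697 were called higher and 128 lower, and among the 3099 dimmest 179 higher and 475 lower. Tested probes above background on all control arrays numbered 12166, on all SDPP arrays 9590 and on all 8 arrays 9360. More probes thus passed the filter through the control diet alone, which favours lower calls among dim probes. Among called probes well above background on all 8 arrays, 1589 were higher and 447 lower. That filter drops probes whose signal falls below background on either diet. Of the 695 calls it removed, 569 were lower and 126 higher. The balance in this subset therefore follows in part from the filter and is not separate evidence of a dependence on signal. The share of higher calls among all called probes was 62.8% in the main scaling. It was 80.3% with median centring and 73.2% with spike-in scaling, but 43.3% with the 75th percentile taken over probes above background on all arrays and 22.6% with the deposited values on their own scale. The median log2 difference of all tested probes was 0.058 in the main scaling and 0.28, 0.34, -0.074 and -0.19 in these 4, in the same order. The deposited values differ from the processed signal in more than scale, so their results here do not measure scaling alone. The spike-in probes themselves averaged 15.4 ± 0.115 on the control arrays and 14.8 ± 0.359 on the SDPP arrays as log2 signal before scaling (SD, n = 4; two-sided exact permutation p = 0.0571).

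**Figure D2:**
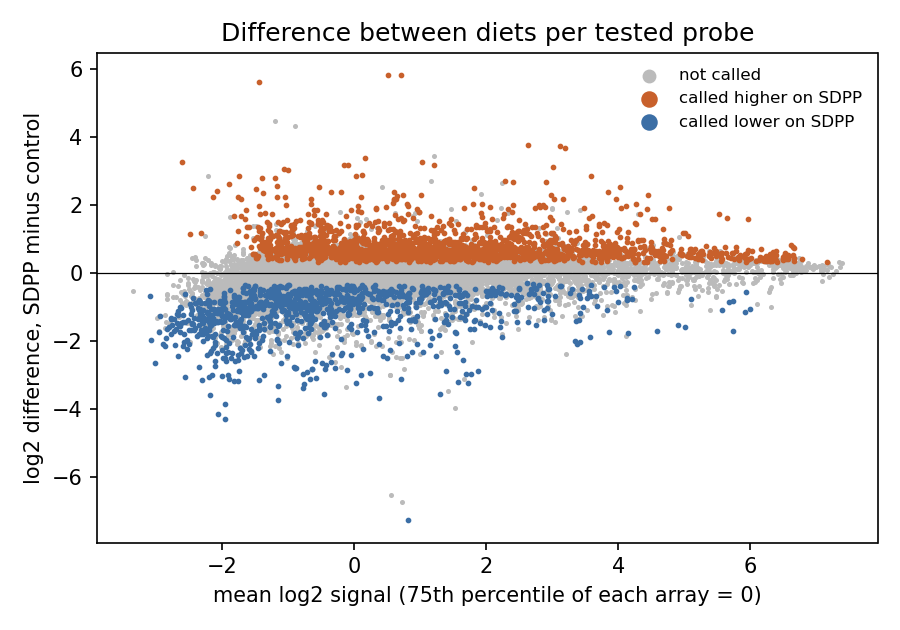
Log2 difference between the diets (SDPP minus control, vertical) against mean log2 signal relative to each array's 75th percentile (horizontal), 1 point per tested probe. The 1715 probes called higher on SDPP and the 1016 called lower are coloured, and lower calls gather at low signal.

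Of 911 transcripts with at least 2 tested probes and a called one, 890 had differences of 1 sign in all their tested probes (97.7%), called or not, and 421 had all their tested probes called. No transcript had probes called in opposite directions.

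At an unadjusted p below 0.05, limma gave 4939 probes, 2941 higher and 1998 lower, where 5% of the tested probes is 619.8. Other splits of the 8 arrays into 4 and 4, some of which keep most of each diet together, gave up to 2932. The direction of the 4939 probes also depended on scaling. With the 75th percentile taken over probes above background on all arrays, 2010 were higher and 2831 lower. With the deposited values, which differ in more than scale, the counts were 893 and 3158. In the main scaling, with a change of at least 2-fold as well, 406 were higher and 797 lower. The balance at 2-fold turned with median centring, at 740 higher and 573 lower, and with spike-in scaling, at 907 and 537. Among probes above background on all 8 arrays it was 316 and 221. That filter drops probes that fall below background on 1 diet. Of probes called by at least 2-fold, 377 of 520 lower and 82 of 377 higher were not above background on every array. This last turn therefore follows largely from the filter.

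Among called probes whose 4 SDPP arrays all lay on 1 side of the control arrays, the rule extended to sequence names gave cDN06P0004N21.F.ab1 and cDN03P0006M03.F.ab1 for increases. These have no gene name here, so the rule as fixed beforehand did not cover them. Part of their control signal, and all SDPP signal of the 2 transcripts given for decreases, was not well above background, so their order of size is not settled. The log2 signal of cDN06P0004N21.F.ab1 was -2.20 ± 2.90 on the control diet and 3.61 ± 0.29 on SDPP (SD, n = 4), a log2 difference of 5.81 with SE 1.24 (limma adjusted p = 0.0175, all 4 SDPP pools above all 4 control pools). Its control values were far apart, at 1.08, -5.00, -4.25 and -0.63 in pools 1 to 4, and it was well above background on 3 of the 4 control arrays. A second probe of this transcript gave a log2 difference of 5.81. The array holds 3 probes for it, and the remaining one was not tested, being well above background on all 4 arrays of neither diet. The call of cDN06P0004N21.F.ab1 was lost without SDPP pool 2, at an adjusted p of 0.0509 in limma. It was kept in 25 of 41 alternative settings, with adjusted p in limma from 0.00191 to 0.738. Transcript cDN03P0006M03.F.ab1 was well above background on all 4 SDPP arrays, at 1.37 ± 0.24 (SD, n = 4), but on only 1 control array, pool 1, at -1.77. Its fitted log2 difference of 5.61 with SE 0.83 (limma adjusted p = 0.00554) therefore rests largely on control signals not well above background, with a control mean of -4.24 ± 1.92 (SD, n = 4).

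For decreases the extended rule gave cDN10P0004M08.F.ab1 and cDN08P0004B17.F.ab1, both well above background on all 4 control arrays and on no SDPP array. The fitted log2 difference of cDN10P0004M08.F.ab1 was -4.31 with SE 0.39 (limma adjusted p = 0.000999), from measured log2 means of 0.20 ± 0.30 and -4.11 ± 0.83 (SD, n = 4). Its mean was lower on SDPP by a bound of 5.39-fold, and its other 2 tested probes were also called lower. For cDN08P0004B17.F.ab1 the fitted log2 difference was -3.58 with SE 0.84 (limma adjusted p = 0.0229), from measured means of -0.39 ± 1.78 and -3.98 ± 0.81 (SD, n = 4). The bound was 3.58-fold, and control pool 2 at -2.97 lay close to the SDPP pools. Both bounds allow for dim SDPP signal but not for the spread between pools, and neither was tested. The call of cDN08P0004B17.F.ab1 was lost in 21 of 41 alternative settings, over which the adjusted p in limma ranged from 0.000511 to 0.738. Those settings include leaving out control pool 1, 3 or 4 or SDPP pool 2, with adjusted p from 0.0539 to 0.0698.

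**Figure D3:**
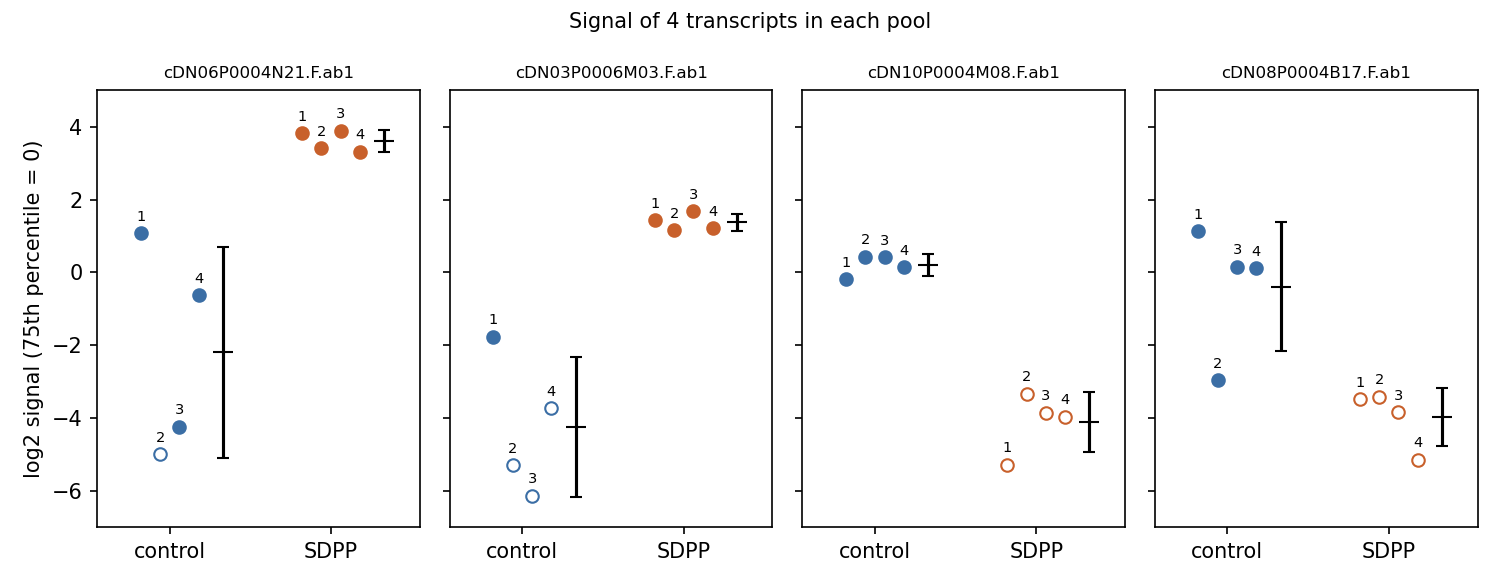
Log2 signal of the 4 transcripts in each pool, relative to the array's 75th percentile, with the pool number above each point, and the mean and SD of each diet as a bar. Filled points are well above background and open points are not; cDN10P0004M08.F.ab1 and cDN08P0004B17.F.ab1 have only open points on SDPP.

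In all, 54 probes were well above background on all 4 control arrays and on no SDPP array. Of these, 42 were called lower, 10 of them by a bound of at least 2-fold, and the 10 belonged to 8 transcripts. The opposite pattern, all 4 SDPP arrays and no control array, was seen in 0 probes. Far fewer probes could show it. Probes above background numbered 12166 on all control arrays and 9590 on all SDPP arrays, with 9360 in both.

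Both slides that carried a pool of each diet gave differences in the same direction as the calls. Of 1344 probes called among the 4 arrays alone on their slides, 97.4% had the same sign in SDPP pool 3 minus control pool 1 on slide 1 and 88.6% in SDPP pool 4 minus control pool 2 on slide 2, with medians of 1.1 and 0.96 on the log2 scale in the direction of the call. This agreement repeats the diet difference in separate samples only if the pools share no RNA, which is not settled. Over all 12325 probes with values on every array, which are not independent replicates, the differences of slides 1 and 2 correlated at only r = 0.162. On both slides 470 probes differed at least 2-fold in the same direction, 230 higher and 240 lower, where unrelated differences would give 186, and 179 differed at least 2-fold in opposite directions. With slide as a fixed block, which leaves the diet contrast to these 2 slides, limma called 0 probes, with 805 at an unadjusted p below 0.05. That fit has 1 residual degree of freedom, so the loss of calls does not show that the differences are absent. In it diet also coincides with position on the slide. The log2 differences of cDN06P0004N21.F.ab1, cDN03P0006M03.F.ab1, cDN10P0004M08.F.ab1 and cDN08P0004B17.F.ab1 were 5.57, 4.99, -4.03 and -3.58 with the block, against 5.81, 5.61, -4.31 and -3.58 without it. Each rests in part on signals not well above background, so these values do not measure the size of the changes.

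Control pool 4 lay close to the average of the other control pools. Over 183 transcripts that differed at least 4-fold among control pools 1 to 3, the signal of control pool 4 departed from the plain average of those 3 pools on the linear scale by a median of 0.115 on the log2 scale, and the best-fitting weights of pools 1, 2 and 3 were 0.337, 0.357 and 0.322. Control pool 4 lay within 0.5 log2 units of that average in 89.6% of these transcripts. The transcript with the widest range among control pools had 5.62, -5.27 and 3.44 in pools 1, 2 and 3, which average to 4.32, and 4.46 in pool 4. In the SDPP group, pool 1 lay near a weighted sum of pools 3 and 4, with weights 0.681 and 0.361 and a median departure of 0.115 over 419 transcripts that differed at least 4-fold between those pools.

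**Figure D4:**
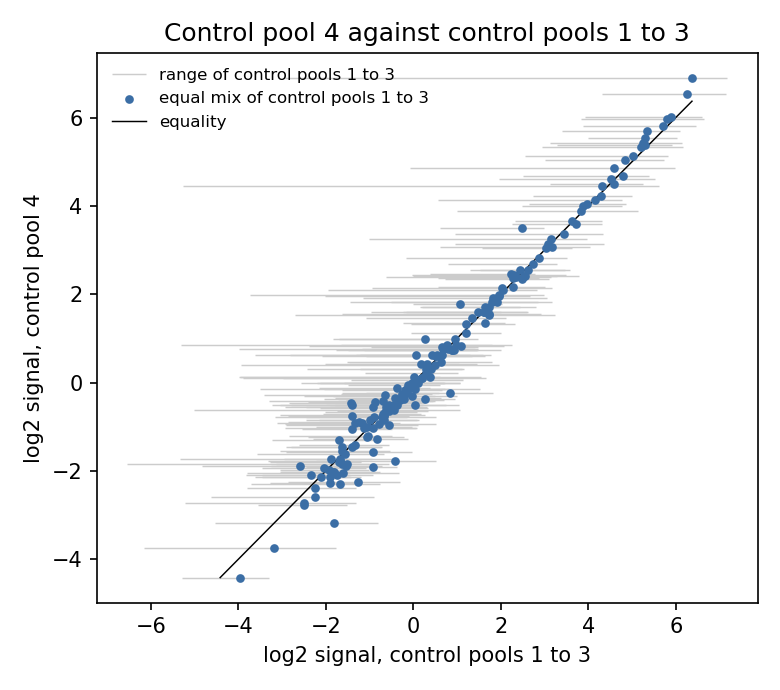
Log2 signal of control pool 4 (vertical) against the equal mix of control pools 1 to 3, averaged on the linear scale (points), and the range of those 3 pools (grey lines), for 183 transcripts that differ at least 4-fold among pools 1 to 3. The points lie along the line of equality, with a median departure of 0.115.

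The number of calls depended on which pools were kept. Without control pool 4 limma called 918 probes, without SDPP pool 1 it called 1443, and without both, 3 against 3, it called 75 (49 higher and 26 lower), with 3174 at an unadjusted p below 0.05. The count was 1378 without control pool 1, 1211 without control pool 3 and 1009 without SDPP pool 2, but 2760 without control pool 2, 3983 without SDPP pool 3 and 2037 without SDPP pool 4. Over all 16 choices of 3 against 3 it ran from 60, without control pool 4 and SDPP pool 2, to 3908, without control pool 2 and SDPP pool 3, with a median of 1080. Without control pool 4 and SDPP pool 1, cDN10P0004M08.F.ab1 was called and the other 3 named transcripts were not, with limma adjusted p from 0.0685 to 0.128. Their log2 differences, 6.27 for cDN06P0004N21.F.ab1, 5.76 for cDN03P0006M03.F.ab1 and -3.57 for cDN08P0004B17.F.ab1, were close to those from all 8 pools. These rest in part on signals not well above background, so their closeness does not show a stable size of change. The transcript count in that setting was 42, and it was 0 with slide as a fixed block.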

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

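Of 24 sets of 4 values examined for a pool far from its group, 1 stood out, where chance would give about 1 in 20. The SD between the copies of a probe within an array was 0.112 on control pool 2, far below the other control arrays. No explanation was tested for it.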

How the results depend on the processing

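Settings that leave out more than 1 array, spike-in scaling and slide as a random block were chosen after seeing the data. The number of called probes, 2731, stayed within 1.5 times under 14 of 42 alternatives and moved further under 28. It was 1506 with normexp, 1649 with the deposited values, 455 with no filter and 1358 with probes above background on at least 1 array, where more dim probes were tested. It was 6549 with array weights, 1665 with spike-in scaling, 0 with slide as a fixed block, 75 for 3 against 3 (without control pool 4 and SDPP pool 1), 0 for 3 against 2 (without control pool 4 and SDPP pools 1 and 2), 1350 for the 4 arrays alone on their slides and 4152 for arrays with an accepted grid. The last sets 3 control arrays against SDPP pool 4 alone, the SDPP pool farthest from the controls, which is assumed to vary as the control pools do, so it says little about stability. Leaving out 1 array gave 918 (control pool 4) to 3983 (SDPP pool 3), and leaving out 1 of each diet gave 60 to 3908. With pool number as a replicate block it was 1391. Same-numbered pools did not deviate together (correlations across probes of -0.00038, 0.0065, -0.025 and 0.025), so no sign of pairing by number was seen. The labels do not say what a pool number marks, and this check cannot exclude a shared tank or day.

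The count at an unadjusted p below 0.05, 4939, was 805 with the slide block, 3174 for that 3 against 3 and 1657 for 3 against 2, and 2766 to 5873 on leaving out 1 array or 1 of each diet. With a 2-fold change as well, 1203 became 1870 with no filter, 537 for probes above background on all 8 arrays, 1849 for at least 1 array, 724 with the slide block, 2474 for the accepted grids, again with 1 SDPP array, and 2777 at 1.5-fold, and lay between 824 and 1830 on leaving out 1 array or 1 of each diet. Apart from changes in the number of probes or arrays, the cause was not tested. The separation of the diets ranged from 0.224 to 0.357 without 1 array and its exact p missed the threshold only without control pool 1, at 0.224. The difference in spots above background passed no threshold and stayed negative without any 1 array. None of the 4 named transcripts changed sign, which their choice by size and non-overlap largely fixed. Of 41 settings, calls were kept in 39 for cDN10P0004M08.F.ab1, 37 for cDN03P0006M03.F.ab1, 25 for cDN06P0004N21.F.ab1 and 20 for cDN08P0004B17.F.ab1. Scan date as a block and the gene list alternatives were not run, for lack of a second scan day and of gene names. Signal over background limits the folds of transcripts seen on 1 diet only.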

Other observations

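All tests of explanations here were chosen after the results were seen, except the counts of splits for probes past 2-fold and for transcripts. For 3 against 3 the prediction was written before its splits were counted, but that choice of pools was made after seeing the data. Some transcripts stepped in a single pool. With the other 3 pools of the diet within 2-fold of each other, control pool 2 was at least 4-fold lower in 21 transcripts and above background in 20 of them, with a median step of -2.93 on the log2 scale. In all 15 of these with further probes those probes stepped by at least 2-fold too. SDPP pool 4 was lower in 19 transcripts but above background in only 1 of them, so the size of its steps is not measured, and the further probes stepped too in 6 of 7. SDPP pool 2 was higher in 8, where the further probes did so in only 1 of 6. Control pool 4 and SDPP pool 3 had 0 such transcripts.

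The array's sequence families were called about equally. The share of tested transcripts called ran from 17.0% to 27.0% over the 18 families of sequence names, and after Benjamini-Hochberg adjustment of Fisher's exact tests no family had a share of calls or of directions apart from the rest, with a smallest adjusted p of 0.288 for direction.

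The diet calls were weighed against the grouping, slides, background and scaling. In 1 of 35 splits, the real one, as many probes were called, 2731 against at most 1 in the others. The same held for 1489 transcripts against at most 1, for 4939 probes at an unadjusted p below 0.05 against 2932, and for 1203 with 2-fold against 597. These counts share the same splits, and 1 of 35 is the smallest share the splits allow. The filter that chose the tested probes also used the diets, which can favour the real split. Chance is argued against, if the 8 pools are separate samples, but not excluded. On both slides that held each diet, control was at position 1 and SDPP at position 2, so position alone is not separated from diet there. The arrays alone on their slides were all at position 1. Of the probes called among them, 86.0% had the same sign within both shared slides, where chance gives 25%. For these probes slide alone and position alone are each argued against. Grid acceptance also went partly with diet, as the grid was not accepted on control pool 1 and SDPP pools 1, 2 and 3. Among the arrays alone on their slides it coincided with diet. On each shared slide both arrays had the same grid status, so grid acceptance alone does not give the shared signs there. Its part in the other calls was not tested. Nor are dim signals the whole cause, since 21.8% of probes above background on all arrays were called. Scaling stays open as a cause of part of the calls and of the balance of directions. The share of calls kept with their sign was 87.6% with median centring but 56.7% with spike-in scaling. It was 48.3% with the deposited, unscaled values, but these differ from the processed signal in more than scale. Some of their cells are empty, and they moved the named log2 differences unequally. That of cDN08P0004B17.F.ab1 went from -3.58 to -5.53, and that of cDN06P0004N21.F.ab1 from 5.81 to 5.60. For 3 against 3, the 10 splits are too few for a share under 0.05, and the real split was the only one (1 of 10) with as many as 75 probes, the next having 0.

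Control pool 4 may hold RNA or fish shared with control pools 1 to 3. Its squared departure from their equal mix was 0.192 of the variance expected of a mean of 3 pools (bootstrap interval over transcripts 0.124 to 0.276). Simulated pools gave at most 0.067 if mixed from the other 3 and at least 0.704 if at the true mean, so the observed ratio lay outside both ranges. The simulated true mean was a log2 mean and the simulated transcripts varied independently, so these ranges cannot decide the question. A separate pool at the true mean would come this near to equal weights with a probability of 0.0142 after allowing for the 8 arrays examined, under a normal model with 2 axes of variation, which argues against a coincidence only as far as that model holds. Background treatment does not account for it, with a ratio of 0.217 from normexp signals. If the pool is not separate, the 4 against 4 p-values, the splits and the agreement between slides overstate the evidence, and the count without it is 918.

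The SDPP pools lay along a line from pool 3 to pool 4, with pools 1 and 2 between them. An effect common to both arrays of slide 2, SDPP pool 4 and control pool 2, is argued against by a correlation of -0.021 across probes between their departures. However, the ends of the line, SDPP pools 3 and 4, are also the SDPP arrays on shared slides, both at position 2. SDPP pools 1 and 2 were alone on their slides at position 1. Slide 1 and position were not tested for this pattern. Dim signal is argued against by the brightest 2326 probes above background on all arrays, where SDPP pool 4 was still 1.44 times as far from the controls as the mean of the other SDPP pools. Shared RNA, with a weight of 0.361 for pool 4 in pool 1, cannot be told apart from 1 axis of variation among separate pools, such as a graded response to the diet, because both place a pool between the other 2.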
